A study of Mus musculus with 7 samples.

How the data were processed

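Messenger RNA was profiled in 7 mouse libraries. The labels describe neural precursors taken from BALB/c embryos at embryonic day 14, transduced in culture with retroviruses carrying an oncogene together with the red fluorescent protein DsRed, and grafted into the brains of adult BALB/c mice after 10 days, with 20000 cells per graft. Wild-type precursors received PDGF-B, a ligand of the platelet-derived growth factor receptors. Precursors lacking the Ink/Arf locus, which encodes the tumour suppressors of Cdkn2a, received EGFRvIII, a truncated and constitutively active form of the epidermal growth factor receptor. Tumours were dissected at the first neurological symptoms, sorted for DsRed by flow cytometry, and sequenced on a BGISEQ-500 instrument. Groups were taken from the sample titles: 3 gliomas labelled PDGF-B, 3 gliomas labelled EGFRvIII, and 1 culture of neural progenitors transduced with PDGF-B. Oncogene and genotype differ together between the glioma groups. The protocol names both poly(A) selection and ribosomal RNA depletion, and which was used is not given in the sources used here.

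The submitters' processing notes name STAR, edgeR and the mm10 build, without versions. The deposited values are log2 CPM (counts scaled by library size), per the file headers of 6 files; the header of the file for EGFRvIII replicate 3 names no unit, and its values have the same floor and range. Each file lists the same 17422 Ensembl genes, so the authors had filtered genes before deposit; the quantifier, the scaling method and the filter are not given in the sources used here. All libraries share a lowest value of -4.12 log2 CPM. The values above it with lower read counts, the only ones checked for this, were all multiples of 0.01 of a step worth 1 read. The tolerance was 0.001 of a step. The deposited values therefore derive from estimated counts with fractions, to which a prior count of 2 was added. Between 36.1% and 38.4% of the values above the floor in each library were whole reads, within 0.02 of a step. Recovered totals ranged from 32513731 to 39062556 reads per library. The recovered reads divided by the authors' effective library sizes give CPM without the prior, which is the CPM printed throughout. Symbols and coordinates came from the GENCODE M21 annotation of GRCm38, the assembly that mm10 denotes. A symbol was found for 17254 IDs and none for 168.

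The design fixed before the data were examined had assumed read counts or unlogged values. Because the deposited values were already on a log2 scale with a prior, they were tested as deposited with limma 3.58.1 in R 4.3.3, using linear models with an intensity trend and robust empirical Bayes moderation. P-values were adjusted by the Benjamini-Hochberg method, and genes were called at an adjusted p of 0.05. Fold changes are differences of mean deposited log2 values and understate the change of genes with few reads. The first comparison used the 6 gliomas, with 4 residual degrees of freedom. The second compared the gliomas labelled PDGF-B with the culture in a fit of all 7 libraries in 3 groups, also with 4 residual degrees of freedom. Its lone culture library has no replicate and is assumed to vary like the gliomas.

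Before the data were examined, 30 gene lists were fixed. Of these, 24 with at least 5 measured members were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. The driver and sex-linked lists, with 6 and 5 measured members, were left out of the tests. Counts of called members are given over all genes and adjusted over the list alone. The genes named were chosen by a rule fixed at the same time. It takes the driver and targeted genes and, in each direction, the 6 called genes of largest fold change with non-overlapping groups and at least 10 CPM in the higher group, leaving out predicted genes. It adds the 3 members of smallest p in each list that passed, the leading called member in each direction for other lists with at least 2 called members, and the 2 most abundant markers of each non-tumour cell type. Genes outside the rule are said to be so where they appear, and some genes that the rule takes are not reported here.

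On data simulated for the real genes, the first comparison recovered 10.4%, 56.7% and 74.2% of genes changed 2-fold, 4-fold and 8-fold, and 6% of its calls were unchanged genes. The second recovered 0%, 28.4% and 39.4%, with 8.2% unchanged genes among its calls. The simulated noise was independent between genes, without differences that many genes of a library share. These shares therefore need not hold for the real gliomas. The alternatives covered other scaling, other pseudocounts, a CPM minimum, voom weights on the recovered reads, a replicate block, a stricter threshold and leaving out each glioma in turn. Library totals without scaling factors, removal of the exon length trend, other pseudocounts for the second comparison, and the gliomas labelled EGFRvIII against the culture were chosen after seeing the data. Count-based tests planned as alternatives were not run, because the deposited values derive from counts with fractions and not from whole counts. For genes with 0 reads in the culture, folds are lower bounds against 3 reads in that library. Intervals at a 95% level for genes with 1 to 3 reads are exact Poisson intervals. Such bounds and intervals cover counting error only. Scripts also used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.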

Results

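RNA from DsRed-sorted cells of mouse high-grade gliomas was sequenced in 3 gliomas labelled PDGF-B, 3 labelled EGFRvIII and 1 culture of PDGF-B-transduced neural progenitors. The series describes the gliomas of each model as independent tumours. Recovered depth was 32695487, 32513731 and 33753684 reads in replicates 1 to 3 labelled PDGF-B, 34306157, 39062556 and 34494098 in those labelled EGFRvIII, and 36061647 in the culture. Mitochondrial genes held 4.20% to 6.14% of CPM in the gliomas and 9.53% in the culture.

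The driver genes were examined first, and they ran against the labels of all 6 gliomas. Egfr (ENSMUSG00000020122, chromosome 11, 16752203 to 16918158, mm10), the epidermal growth factor receptor gene, stood at 4552 ± 833 CPM (SD, n = 3) in the gliomas labelled PDGF-B and at 31.2 ± 8.63 CPM (SD, n = 3) in those labelled EGFRvIII. The log2 fold change was 7.20 ± 0.26 (SE, limma adjusted p = 0.000187). Pdgfb (ENSMUSG00000000489, chromosome 15, 79995874 to 80014977) stood at 3.27 ± 1.49 CPM in the gliomas labelled PDGF-B and at 316 ± 60.9 CPM in those labelled EGFRvIII (SD, n = 3 each). Its log2 fold change was -6.65 ± 0.34 (SE, limma adjusted p = 0.000838). The PDGF-B culture held 245 CPM of Pdgfb and 282 CPM of Egfr. Cdkn2a (ENSMUSG00000044303, chromosome 4, 89274471 to 89294653), which the labels describe as deleted in the EGFRvIII model through the Ink/Arf locus, was lower in the gliomas labelled PDGF-B, at 3.82 ± 1.05 CPM against 19.98 ± 7.84 CPM (SD, n = 3 each, log2 fold change -2.31 ± 0.39, SE, limma adjusted p = 0.0318). The culture held 10.7 CPM of Cdkn2a. The Cdkn2a call ended in 5 of the 6 fits that left out 1 glioma, all but the one without PDGF-B replicate 3, with log2 fold changes from -2.69 to -2.08 and limma adjusted p from 0.0171 to 0.123. Which exons the deletion removes, and whether the transgenes are of mouse or human sequence, is not given in the sources used here, so Cdkn2a reads can come from remaining exons and transgene reads can map in part. Cdkn2b, Pdgfra and Pdgfrb did not pass the test, with limma adjusted p of 0.928, 0.308 and 0.288. Pdgfra stood at 3453 ± 1563 CPM in the gliomas labelled PDGF-B and 1693 ± 260 CPM in those labelled EGFRvIII (SD, n = 3 each). Egfr and Pdgfb contradict the labels. The Cdkn2a level was not lower in the gliomas described as lacking the locus, but reads from remaining exons limit what it shows. Every direction given here therefore refers to gliomas as labelled, and no library was moved to another group.

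**Figure D1:**
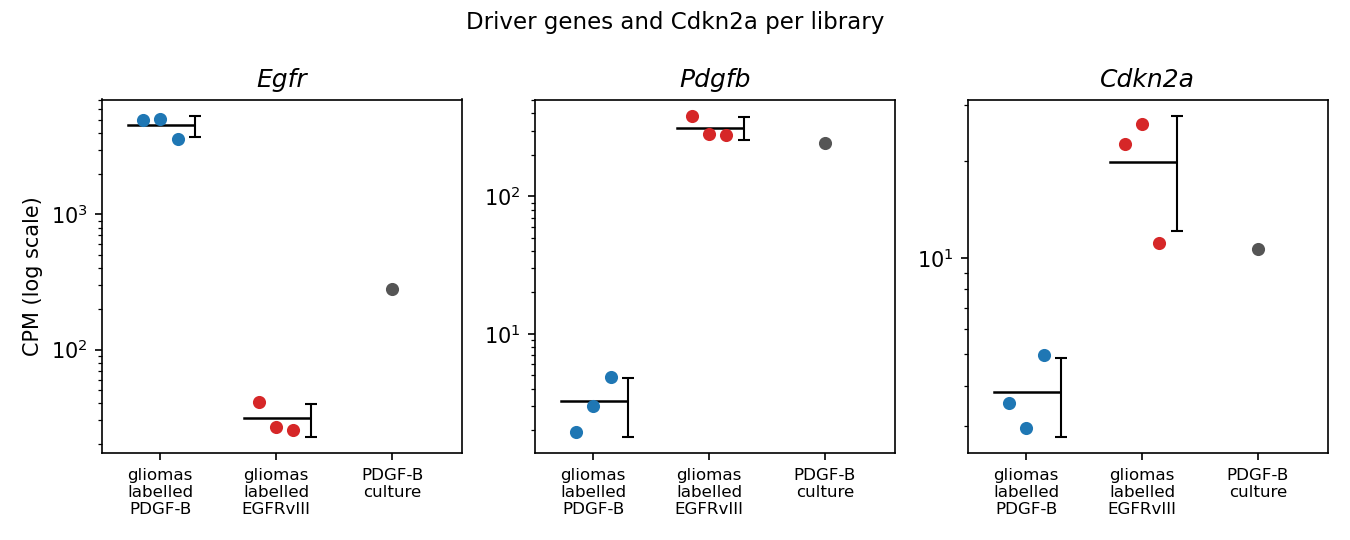
CPM on a log scale of Egfr, Pdgfb and Cdkn2a in each library (points), with the mean (line) and SD (bar) of the 3 gliomas of each label; the culture is 1 library. Egfr lies at 4552 CPM on average in the gliomas labelled PDGF-B and 31.2 CPM in those labelled EGFRvIII, and Pdgfb at 3.27 and 316 CPM.

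The first comparison asked how the gliomas of the PDGF-B and EGFRvIII models differ. The microglia and macrophage list passed the preset list test as lower in the gliomas labelled PDGF-B, and the oligodendrocyte precursor and myelin lists as higher with 2 of 23 and 4 of 17 members called; none of these lists passed with an estimated correlation (adjusted p = 0.436 for each). In all, 583 of 17422 genes were called, 125 higher and 458 lower in the gliomas labelled PDGF-B. Besides Egfr, the called genes of largest fold change that were higher in the gliomas labelled PDGF-B were Pdlim3, Nxf3, Neu4, Adarb2 and L1cam. Neu4, a sialidase, stood at 155 ± 75.7 CPM against 5.68 ± 7.07 CPM (SD, n = 3 each, log2 fold change 5.43 ± 0.87, SE, limma adjusted p = 0.0309). L1cam, a neural cell adhesion molecule, had a log2 fold change of 4.10 ± 0.40 (SE, limma adjusted p = 0.0163). Besides Pdgfb, those lower were Apoc1, Gpnmb, Cd300lb, Igf1 and Slc40a1. Slc40a1, which encodes the iron exporter ferroportin, stood at 2.90 ± 0.40 CPM against 71.2 ± 24.0 CPM (SD, n = 3 each, log2 fold change -4.54 ± 0.31, SE, limma adjusted p = 0.00441). Apoc1, an apolipoprotein gene, stood at 1.43 ± 0.43 CPM against 93.6 ± 71.6 CPM (SD, n = 3 each).

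Of 20 measured microglia and macrophage genes, 18 were called, all lower in the gliomas labelled PDGF-B, and 20 were lower adjusted over the list alone. The median log2 fold change was -3.35 (camera adjusted p = 6.86e-22, adjusted p = 0.436 with an estimated correlation). Cx3cr1, the microglial fractalkine receptor, stood at 65.5 ± 30.7 CPM in the gliomas labelled PDGF-B and 556 ± 34.7 CPM in those labelled EGFRvIII. P2ry12, a purinergic receptor of microglia, stood at 27.1 ± 1.26 and 217 ± 84.8 CPM, and Trem2 at 11.9 ± 8.002 and 182 ± 93.0 CPM (SD, n = 3 each). Among abundant markers, C1qa stood at 119 ± 87.2 and 1592 ± 1200 CPM, while Lyz2, at 218 ± 342 and 1655 ± 777 CPM, did not pass the test (SD, n = 3 each). Because the libraries came from cells sorted for DsRed, these levels were measured in the sorted fraction. In this fraction the mean log2 CPM of the list was 4.25, 4.67 and 6.09 in replicates 1 to 3 labelled PDGF-B and 8.04, 9.24 and 8.12 in those labelled EGFRvIII.

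Of 23 measured oligodendrocyte precursor genes, 2 were called higher in the gliomas labelled PDGF-B, and 7 were higher adjusted over the list alone, with a median log2 fold change of 0.70 (camera adjusted p = 2.02e-09, adjusted p = 0.436 with an estimated correlation). The called genes were Neu4 and Gpr17, a receptor of committed precursors, which stood at 749 ± 449 against 101 ± 23.2 CPM (SD, n = 3 each). Of 17 myelinating oligodendrocyte genes, 4 were called higher, and adjusted over the list alone 7 were higher and 1 lower (median 0.54; camera adjusted p = 0.00280, adjusted p = 0.436 with an estimated correlation). Myrf, a transcription factor of myelination, stood at 38.5 ± 11.8 against 7.18 ± 3.89 CPM (SD, n = 3 each). The myelin list missed the threshold without EGFRvIII replicate 1, where its median fell to 0.20 (camera adjusted p = 0.0699). The EGF and PDGF family list had 3 members called higher and 1 lower, and its called members include the drivers themselves (median 0.44, or 0.74 without PDGF-B replicate 3; camera adjusted p = 0.0191, adjusted p = 0.436 with an estimated correlation). Erbb3, a receptor of the same family as Egfr, stood at 132 ± 13.6 against 56.6 ± 8.29 CPM (SD, n = 3 each).

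**Figure D2:**
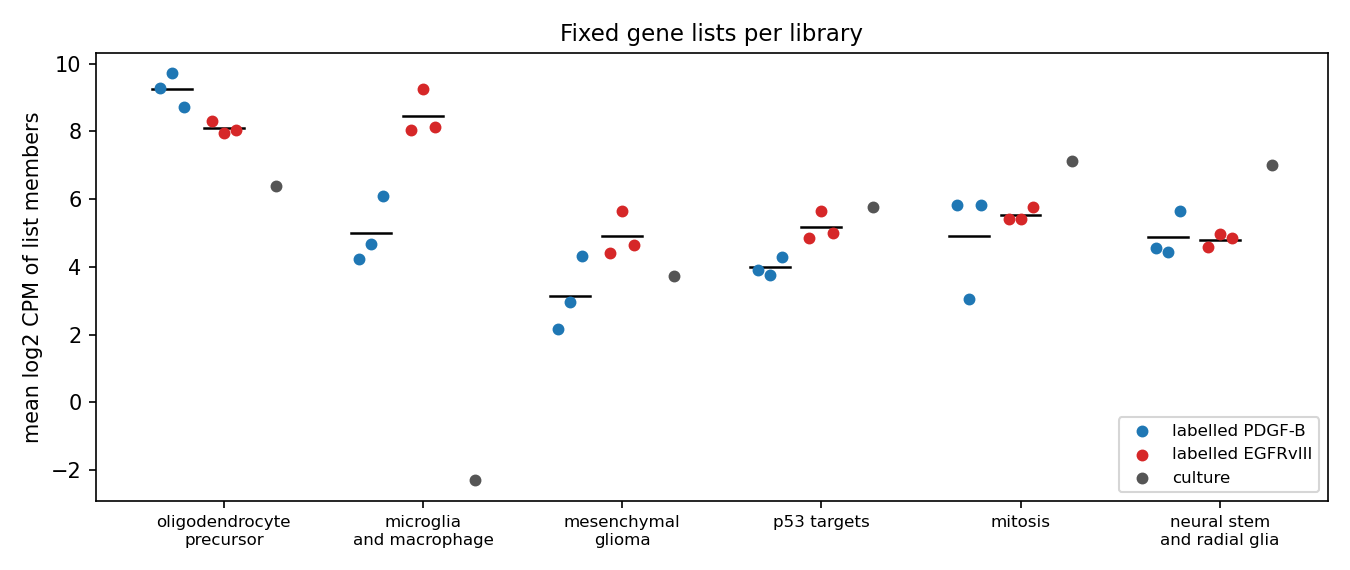
Mean log2 CPM of the measured members of 6 fixed gene lists in each library (points), with the mean of the 3 gliomas of each label (line). The microglia and macrophage list lies at 4.25 to 6.09 in the gliomas labelled PDGF-B and 8.04 to 9.24 in those labelled EGFRvIII, and the mitosis list of PDGF-B replicate 2 lies at 3.07.

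Lists of p53 targets, mesenchymal glioma genes and immediate early genes were lower in the gliomas labelled PDGF-B, each with an adjusted p of 0.436 with an estimated correlation, and the macrophage list moved with them. Of 25 p53 target genes, 3 were called lower, 18 adjusted over the list alone (median -1.02; camera adjusted p = 2.02e-09). Pmaip1, which encodes the apoptosis regulator Noxa, stood at 3.605 ± 0.42 against 21.7 ± 6.54 CPM, Btg2 at 12.4 ± 5.42 against 62.4 ± 19.4 CPM, and Eda2r at 13.4 ± 5.52 against 75.5 ± 43.3 CPM (SD, n = 3 each). Of 25 mesenchymal genes, 1 was called lower, 12 adjusted over the list alone, with 1 higher (median -1.88; camera adjusted p = 3.73e-07). It was Tgfb1, transforming growth factor beta, at 8.88 ± 5.73 against 80.0 ± 21.4 CPM (SD, n = 3 each). Of 20 dissociation and immediate early genes, 4 were called lower, 11 adjusted over the list alone (median -0.99; camera adjusted p = 4.80e-08), led by Atf3 at 16.5 ± 6.50 against 133 ± 52.9 CPM (SD, n = 3 each). The endothelial list (median -1.50; camera adjusted p = 0.00164, adjusted p = 0.436 with an estimated correlation) had 0 of 11 members called, and adjusted over the list alone 5 were lower and 1 higher. The hypoxia and glycolysis list (median -0.89; camera adjusted p = 0.000666, adjusted p = 0.766 with an estimated correlation) had 0 of 26 called, with 10 at an unadjusted p under 0.05 in limma. The Notch and Wnt list (median 0.50; camera adjusted p = 0.0191, adjusted p = 0.436 with an estimated correlation) had 0 of 19 called, with 4 at an unadjusted p under 0.05 in limma, and missed the threshold without PDGF-B replicate 3 (camera adjusted p = 0.170) and without EGFRvIII replicate 2 (camera adjusted p = 0.0559).

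The mitosis and DNA replication lists passed the preset test as lower in the gliomas labelled PDGF-B, with medians of -0.62 and -0.69 (camera adjusted p = 0.0441 and 0.0140, adjusted p = 0.971 and 0.937 with an estimated correlation), and both depended on single libraries. The mean log2 CPM of the mitosis list was 3.07 in PDGF-B replicate 2, against 5.83 in the other gliomas labelled PDGF-B and 5.41 to 5.76 in those labelled EGFRvIII. Without it the medians were 0.34 (camera adjusted p = 0.000323) and 0.045 (camera adjusted p = 0.671). The mitosis list also missed the threshold without EGFRvIII replicates 1, 2 and 3 (medians -0.70, -0.65 and -0.50; camera adjusted p = 0.0699, 0.0525 and 0.190), and the DNA replication list without EGFRvIII replicate 3 (median -0.52; camera adjusted p = 0.147). Without PDGF-B replicates 1 and 3 the mitosis medians were -1.12 and -1.07, and without replicate 3 the DNA replication median was -1.14. No member of either list was called, and none had an unadjusted p under 0.05 in limma. The other lists did not pass, with camera adjusted p of 0.0709 for forebrain regional genes, 0.220 for mural and fibroblast genes, 0.249 for the interferon response, 0.340 for neural stem genes, 0.480 and 0.640 for MHC class I and II, 0.877 for astrocyte, neuroblast, mature neuron and MAPK output genes, and 0.985 for extracellular matrix and cholesterol synthesis genes. Forebrain regional genes passed without PDGF-B replicate 2 or EGFRvIII replicate 2 (camera adjusted p = 0.0335 and 0.0390), interferon genes without the same libraries (0.0383 and 0.000987), mural and fibroblast genes without PDGF-B replicate 3 (0.0127), and cholesterol genes without EGFRvIII replicate 1 (0.00911). Among these lists, the direction of the test, the median and the mean were not all of 1 sign for astrocyte, mature neuron, MAPK output, interferon, extracellular matrix and cholesterol genes. In the astrocyte list S100b was called higher, at 77.3 ± 14.1 against 16.5 ± 6.80 CPM, and Apoe lower, at 1156 ± 1120 against 9414 ± 2199 CPM (SD, n = 3 each). The extracellular matrix list had 3 members called higher and 2 lower, led by Col4a1, a basement membrane collagen, at 173 ± 37.2 against 48.1 ± 3.48 CPM, and by Timp2, a metalloproteinase inhibitor, at 140 ± 10.4 against 339 ± 83.6 CPM (SD, n = 3 each).

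Groups did not overlap in all 583 called genes, which being called largely requires, and in 3997 of the 17422 genes (22.9%). Chance gives 10% for 3 against 3 on average over splits. A single split can depart from 10% because genes vary together, so the 22.9% does not show how many genes differ. The call count changed with single libraries. It was 4 and 7 without PDGF-B replicates 1 and 2, 21, 15 and 7 without EGFRvIII replicates 1 to 3, and 1282 without PDGF-B replicate 3. That library lay nearest to the other group on the first principal component of the 6 gliomas (60.1% of the variance), at -4.76 against -77.3 and -78.1 for replicates 1 and 2 and 34.2 to 88.0 for the gliomas labelled EGFRvIII. Its Spearman correlation was 0.965 with EGFRvIII replicate 3, against 0.963 and 0.949 with replicates 1 and 2 of its own group. At an adjusted p of 0.01 there were 7 calls. Egfr, Pdgfb and Slc40a1, together with the predicted gene Gm12606, which was named after its values were seen, were called whichever glioma was left out.

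The second comparison set the gliomas labelled PDGF-B against the progenitor culture. It was meant to bear on what changes between transduced cells in culture and tumours. Because the driver genes contradict the glioma labels here too, oncogene and genotype may differ along with growth as a tumour. The comparison cannot separate these differences. Cell composition may differ too: the microglia and macrophage list had a mean log2 CPM of 4.25 to 6.09 in these gliomas and -2.29 in the culture. How far such RNA carries the interferon, MHC and other lists that were higher in the gliomas was not tested. Directions again refer to gliomas as labelled. Pdgfb was lower in them, with a log2 fold change of -6.30 ± 0.47 (SE, limma adjusted p = 0.00125) and Egfr higher, with one of 3.99 ± 0.36 (SE, limma adjusted p = 0.00192). The microglia and macrophage, interferon, MHC and oligodendrocyte lists passed the preset list test as higher in the gliomas, and lists that passed as lower included neural stem, neuroblast and forebrain regional genes. None of the 13 lists that passed did so with an estimated correlation (adjusted p from 0.242 to 0.511). In all, 1647 genes were called, 1346 higher and 301 lower in the gliomas labelled PDGF-B.

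The complement genes C1qa, C1qb and C1qc, the protease gene Ctss, the homeobox gene Meox1 and the interferon-induced gene Oasl2 were the called genes of largest fold change that were higher. C1qb stood at 95.8 ± 63.1 CPM (SD, n = 3) with 0 reads in the culture, at least 1103-fold higher, and Oasl2 at 43.2 ± 22.2 CPM (SD, n = 3) with 0 reads, at least 498-fold higher. Meox1 stood at 69.5 ± 19.7 CPM (SD, n = 3) against 1 read in the culture, a ratio of 2402 with a counting interval of 431 to 94854. Of 20 microglia and macrophage genes, 18 were called higher, 20 adjusted over the list alone. The median log2 fold change was 7.56, or 7.47 with the 4 genes without culture reads at their bounds (camera adjusted p = 1.44e-19, adjusted p = 0.242 with an estimated correlation). Of 22 interferon response genes, 11 were called higher, 18 adjusted over the list alone (median 3.27; camera adjusted p = 2.49e-09, adjusted p = 0.499 with an estimated correlation). Ifi27, an interferon-induced gene, stood at 73.4 ± 11.9 CPM (SD, n = 3) against 0.58 CPM in the culture. MHC class I genes had 6 of 15 called higher, 8 adjusted over the list alone (median 2.35; camera adjusted p = 0.000129, adjusted p = 0.511 with an estimated correlation). MHC class II genes had 0 of 7 called, 4 higher adjusted over the list alone, and 5 at an unadjusted p under 0.05 in limma (median 5.45; camera adjusted p = 0.00760, adjusted p = 0.511 with an estimated correlation).

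Of 23 oligodendrocyte precursor genes, 16 were called higher, 20 adjusted over the list alone (median 2.80; camera adjusted p = 4.90e-12, adjusted p = 0.242 with an estimated correlation). Cspg4, which encodes the precursor marker NG2, stood at 1065 ± 285 CPM (SD, n = 3) against 101 CPM in the culture, and Cspg5 at 1802 ± 553 CPM (SD, n = 3) against 160 CPM. Of 17 myelinating oligodendrocyte genes, 10 were called higher, 14 adjusted over the list alone (median 2.55; camera adjusted p = 4.98e-08, adjusted p = 0.242 with an estimated correlation), among them Bcas1 at 581 ± 54.8 CPM (SD, n = 3) against 70.8 CPM. Erbb3 stood at 132 ± 13.6 CPM (SD, n = 3) against 3.36 CPM, with a log2 fold change of 5.26 ± 0.26 (SE, limma adjusted p = 0.000310), in a list that did not pass.

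Of 18 neural stem and radial glia genes, 7 were called lower, and adjusted over the list alone 12 were lower and 1 higher (median -1.80; camera adjusted p = 4.25e-07, adjusted p = 0.242 with an estimated correlation). Hes5, a Notch effector, stood at 4.90 ± 1.52 CPM (SD, n = 3) against 49.4 CPM in the culture, and Prom1 at 1.49 ± 1.18 CPM (SD, n = 3) against 35.0 CPM. Of 15 neuroblast and interneuron precursor genes, 5 were called lower and 2 higher (median -2.15; camera adjusted p = 0.00760, adjusted p = 0.242 with an estimated correlation); adjusted over the list alone, 9 were lower and 3 higher. Dlx1, an interneuron transcription factor, stood at 0.42 ± 0.20 CPM (SD, n = 3) against 24.9 CPM. Of 14 forebrain regional genes, 7 were called lower and 1 higher, and 8 and 1 adjusted over the list alone (median -2.73; camera adjusted p = 4.25e-05, adjusted p = 0.242 with an estimated correlation). Zdbf2, Dgkk, Prdm16, Gjc1 and Otx1 were among the called genes of largest fall. Zdbf2 had 3 reads over the gliomas labelled PDGF-B against 33.0 CPM in the culture, a ratio of 1132 with a counting interval of 387 to 5491.

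The p53 target list was lower in the gliomas labelled PDGF-B, with 10 of 25 called, 18 adjusted over the list alone (median -1.77; camera adjusted p = 1.16e-09, adjusted p = 0.242 with an estimated correlation). Trp53inp1 stood at 54.3 ± 3.28 CPM (SD, n = 3) against 305 CPM in the culture. Cholesterol synthesis genes had 2 of 23 called lower, 12 adjusted over the list alone (median -1.39; camera adjusted p = 6.86e-08, adjusted p = 0.511 with an estimated correlation), led by Cyp51 at 92.9 ± 10.5 CPM (SD, n = 3) against 305 CPM. The mitosis list had 0 of 25 members called, with 8 at an unadjusted p under 0.05 in limma, and the DNA replication list 1 of 23, Ccne1. Neither had any called adjusted over the list alone. Their medians were -2.33 and -2.25 (camera adjusted p = 2.25e-07 and 1.26e-08, adjusted p = 0.511 for both with an estimated correlation). Without PDGF-B replicate 2, the library with the low mitosis level of 3.07, both lists still passed and the medians were -1.39 and -1.38. Lists that did not pass had camera adjusted p of 0.0784 for endothelial, 0.0876 for Notch and Wnt, 0.231 for mature neuron, 0.239 for dissociation and immediate early, 0.242 for astrocyte, 0.275 for mural and fibroblast, 0.339 for mesenchymal, 0.357 for extracellular matrix, 0.542 for MAPK output, 0.735 for hypoxia and glycolysis and 0.861 for EGF and PDGF family genes. Of these, endothelial genes passed without PDGF-B replicate 1 (camera adjusted p = 0.0225) and dissociation and immediate early genes without replicate 2 (0.0272). Astrocyte, mesenchymal, hypoxia, and Notch and Wnt genes passed without replicate 3 (0.0426, 0.0401, 0.0401 and 0.0426). The test and the mean differed in sign for the dissociation and hypoxia lists.

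The culture is a single library, so this comparison cannot separate its condition from that library. With only the gliomas labelled PDGF-B and the culture in the fit, 721 genes were called, 624 higher and 97 lower; without PDGF-B replicates 1, 2 and 3 the full fit called 854, 1054 and 2303.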

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

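The library totals, the exon length correction and the pseudocounts of the second comparison were chosen after seeing the data. Between the glioma groups, the 583 calls (125 higher, 458 lower in the gliomas labelled PDGF-B) ranged from 516 to 693 under other scaling, pseudocounts, voom weights, a minimum of 1 CPM, the exon length correction and the fit of 7 libraries, and no called gene changed sign. At an adjusted p of 0.01 the counts were 7, 3 and 4, as fewer genes pass a stricter threshold. Leaving out each glioma gave 4 to 1282 calls, with 2 to 308 higher and 2 to 974 lower. Fewer samples may be part of the drop, which was not tested. The rise came without PDGF-B replicate 3, the library of its group nearest to the other group, in a fit with as few samples. Of 32 called genes named in this comparison, 25 to 29 lost their call without any 1 of the 5 gliomas other than PDGF-B replicate 3, 3 with voom weights and 26 with the block described next, and 0 reversed. Same-numbered gliomas had Spearman correlations of 0.935, 0.889 and 0.965. A separate pairing check, on another measure, gave them correlations of 0.197, -0.05 and -0.11, and gave differently numbered gliomas -0.285 to 0.243. The values of that check show no common pairing by replicate number. With so few libraries per group, such a check cannot exclude one. A replicate block left 18 calls, 5 higher and 13 lower, by a fit with fewer residual degrees of freedom. The 12 lists that passed camera at the preset correlation fell to 0 with an estimated correlation and 0 with fry, the cause of which was not tested beyond the list correlations themselves; leaving out each glioma gave 10 to 13. The mitosis and DNA replication medians turned to 0.34 and 0.045 without PDGF-B replicate 2, and ranged from -1.12 and -1.14 up to those values as each glioma was left out. With only the gliomas labelled PDGF-B and the culture, fewer samples estimate the spread. There the 1647 calls against the culture (1346 higher, 301 lower) fell to 721 (624 higher, 97 lower). They ranged from 854 to 2303 when each glioma labelled PDGF-B was left out, with 779 to 1655 higher and 75 to 648 lower. Of 56 called genes named in this comparison, 16 lost their call in the smaller fit, 1 to 12 when a glioma labelled PDGF-B was left out, 6 with log2(CPM + 1), 2 with log2(CPM + 0.1) and 3 with library totals, and 0 reversed. The gliomas labelled EGFRvIII were not left out of this fit. The 13 lists that passed fell to 0 with an estimated correlation, and 8 of them passed with fry, which the mitosis, DNA replication, cholesterol and both MHC lists did not. Library totals moved the median log2 fold change of all genes to 0.155 in this comparison. The no-filter alternative equals the reported fit, because all deposited genes were tested, and the planned count-based tests were not run. At this depth of 32513731 to 39062556 reads, genes with 3 or fewer reads in the culture carry the wide counting intervals given for them.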

Other observations

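The comparison of the gliomas labelled EGFRvIII with the culture, and every test here except the macrophage tracking and chromosome window tests, was chosen after its result had been seen. Those tests were fixed before their own results were known, but the patterns they address had been noticed in the same data. The gliomas labelled EGFRvIII, whose Pdgfb level is close to that of the culture, differed from it in 1663 genes by limma, 1429 higher and 234 lower; the same single culture library serves both comparisons, so their calls are not independent. All 20 measured microglia and macrophage genes were called higher, with a median log2 fold change of 11.16, or 10.96 with genes lacking culture reads at their bounds. Of 23 oligodendrocyte precursor genes 8 were called higher (median 1.65), and of 25 mesenchymal genes 6 were called higher (median 0.64). Of 18 neural stem genes 7 were called lower (median -2.12), and of 19 Notch and Wnt genes 4 were called lower (median -1.01). Bcas1, a gene of newly formed oligodendrocytes, stood at 400 ± 16.4 CPM (SD, n = 3) against 70.8 CPM, with a log2 fold change of 2.495 ± 0.24 (SE; limma adjusted p = 0.00134). The lists were not tested as sets in this comparison.

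Xist and the Y-linked gene Ddx3y belong to a fixed list of sex-linked genes but lie outside the naming rule, and were named after their values were seen. Xist stood between 2033 and 3258 CPM in every library. Ddx3y stood at 3.09, 2.58 and 6.81 CPM in replicates 1 to 3 labelled PDGF-B, at 22.9 CPM in EGFRvIII replicate 3, at 0 in EGFRvIII replicates 1 and 2 and at 0.0289 CPM in the culture. Lists too small to test had few measured members: 3 of 17 lymphocyte, 4 of 7 erythroid and 4 of 30 Hox genes, and 2 of 28 histone symbols. The histone symbols hold old and new names of the same genes. Of these members, 1 lymphocyte gene was called, lower in the gliomas labelled PDGF-B.

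The driver genes ran opposite to the glioma labels. In 6 of 6 gliomas the other model's driver gene was the more abundant of the pair, and out-of-place gliomas were found under both labels. An exchange of the labels of the glioma groups needs this, but the count restates the pattern that raised the question. The order of the pair is also a weak mark, because the PDGF-B culture held more Egfr than Pdgfb, at 282 and 245 CPM. Correct labels with Pdgfb RNA kept in the tumours are argued against by a Pdgfb level in the gliomas labelled PDGF-B that differs from the culture by -6.30 on the log2 scale. The predicted noncoding gene Gm12606 (chromosome 4, 89235699 to 89273403, minus strand), named after its values were seen, begins 1068 bases downstream of Cdkn2a on the same strand. It stood at 22.5 ± 8.27 CPM (SD, n = 3) in the gliomas labelled PDGF-B, with 2 reads in all over those labelled EGFRvIII and 0 in the culture. Transcription running past a deletion in this locus might give this. The pattern is not particular to the locus, however. The predicted gene Gm10182 on chromosome 9, also named after its values were seen, stood at 11.9 ± 6.62 CPM in the gliomas labelled PDGF-B and at 0 CPM in those labelled EGFRvIII (SD, n = 3). An exchange of labels is therefore a candidate explanation that these data cannot settle without the tumours' records, and no regrouping was made.

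The 458 genes lower in the gliomas labelled PDGF-B may in part reflect more microglia and macrophage RNA in the libraries labelled EGFRvIII, but the test made of this cannot separate it from other differences. Outside the marker list, 56.3% of 439 such genes followed the macrophage score within the groups at a correlation above 0.8, against 7.52% to 13.0% in 1000 random sets matched on expression. Within the groups, however, the score had a correlation of 0.969 with the first principal component of the gliomas, which also separates the groups, so genes that differ along it for any cause can follow the score. Checks added after this result do not separate these either. Of the 124 higher genes, 12.9% fell with the score at a correlation below -0.8, against 2.42% to 10.5% in random sets. Of the 34 lower genes with a culture level of at least 50% of that in the gliomas labelled EGFRvIII, 38.2% followed the score. Genes that the culture itself expresses thus followed the score in part, and no random sets were drawn for them. The most abundant markers, Lyz2 and C1qa, stood at 1655 and 1592 CPM in the gliomas labelled EGFRvIII, though the cells had been sorted for DsRed. How such RNA came into the sorted fraction was not tested, and the purity of the sort was not examined here. Of the 20 list genes, 3 reached 1 CPM in the culture, and 0 are in another list. Of the 458 lower genes, 268 stood under 1 CPM in the culture, but the share over all genes is not given here for comparison. Of 25 p53 targets, 6 followed the score at a correlation above 0.8, and no random sets were matched to these targets. In the culture, 18 of them were at least as high as in the gliomas labelled EGFRvIII. The exon length trend, strongest in EGFRvIII replicate 2, is argued against as the whole cause because 432 of the 458 genes stayed called once it was removed. For the 583 calls as a whole, the 10 possible splits of 6 gliomas are too few for a share under 0.05; the real split gave 583 and the highest other split 0, so 1 of 10 gave as many, and the biological difference between the models and their genotypes stays open and untested.

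In EGFRvIII replicate 1, genes on chromosomes 1 and 10 were raised against the median of the other 5 gliomas, by a median log2 of 0.50 over 629 genes and 0.30 over 512 genes; outside these, the largest shift of a chromosome in a glioma was -0.11, that of chromosome 1 in EGFRvIII replicate 2. Medians were above 0.1 in 100% of the 22 windows of at least 50 consecutive genes along both chromosomes, against 5 of 176 windows on other chromosomes of that library. Window medians ranged from 0.38 to 0.62 on chromosome 1 and from 0.13 to 0.47 on chromosome 10, so the shift varied along chromosome 10. Extra copies of both chromosomes in part or all of the cells would raise windows along their length and may be the source. A shift of 0.58 would follow from 3 copies in place of 2. A GC content or exon length bias is argued against by a shift of 0.419 that remained after both trends were removed, from 0.444 before. No DNA measurement was analysed here, so a copy number change remains a hypothesis.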
